A study of Mus musculus with 6 samples.

How the data were processed

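Genomic DNA of mouse cells was immunoprecipitated with an antibody against 5-hydroxymethylcytosine (5hmC) or against 5-methylcytosine (5mC) and sequenced. Per the labels' protocols, sonicated DNA was end-repaired and ligated to paired-end adapters before the precipitation, 500 ng of ligated DNA entered each reaction, the captured DNA was amplified for 14 to 16 cycles, and fragments of 300 to 500 bp were gel-purified. Such a precipitation measures enrichment over stretches far longer than a single CpG. It gives neither the level of a mark at a single cytosine nor whether both marks lie on the same molecule. The captured amount also depends on how many modified cytosines a fragment carries, so regions rich in CpG are captured more readily than regions with few CpG.

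The submitters' processing notes name CASAVA 1.8, Bowtie 0.12.7, MACS 1.4.1 and the mouse build mm9. Each deposited file holds 1 peak list of 1 library, with chromosome, start, end, peak name and a score per peak. The score is the authors' peak caller's value, and per the deposited files its lowest value was 50.00 or 50.01 in each of the 6 lists. It was read here as 10 times the negative log10 of the peak's p-value, which is what this version of MACS is known to write. The files do not state this. Scores were used to rank or filter peaks within a list and to describe each list. Scores depend on depth, so a difference in score between lists was not read as a difference in a mark. A score of exactly 3100 was the most frequent of the high scores and recurred in each list, and the highest score of each list lay above it. What this value stands for is not given in the sources used here. Whether an input or other control library was used, the settings of the peak caller, the treatment of duplicate reads and the number of reads per library are not given in the sources used here. The depth behind each list is therefore unknown. A deeper library gives more peaks and higher scores from the same DNA, so peak numbers and covered lengths mix the mark with the depth.

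Libraries were grouped from the titles in the labels into 3 stages and 2 marks, with 1 library per stage and mark. No replicate error exists and no test between stages was possible, so no p-values are given. Shares of peaks are given with 95% Wilson intervals, which cover counting error only. Neighbouring peaks are not independent, and the spread between cultures is not measured. The lists held no overlapping peaks within a list.

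Peaks of 2 lists were counted as overlapping from 1 bp. The expected share came from 100 random placements of the counted peaks on their own chromosome with bedtools shuffle (bedtools 2.31.1), between the first and the last position that any of the 6 lists covers. Assembly gaps were not left out, since no mm9 sequence was used here. After the data were examined, a second expectation was added in which each counted peak was moved by 10 to 50 kb in a random direction, again 100 times. It keeps the regional density of peaks and is the stricter comparison. Covered base pairs were summed in windows of 100 kb. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap counting was tested on simulated data with 9 runs of 263872 simulated peaks each, with 0 peaks placed wrongly, and gave the same number as bedtools for each of the 30 ordered list pairs.

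Before the data were examined, the alternatives were fixed as a score of at least 100, an overlap of at least 50% of the counted peak, the centre of the counted peak inside the other peak, the same number of best-scoring peaks from each list, peaks within 1000 bp joined, autosomes only, and windows of 1 Mb. The regions named in the text were also chosen by a rule set at that point, as the 3 windows of 100 kb with the largest gain and the 3 with the largest loss of each mark from the fibroblast to the iPS list, and the best-scoring peak of each list. Regions outside this rule are said to be chosen after their values were seen. Coordinates are on mm9, counted from 1. No annotation of mm9 was used here, and the gene table at hand is on another build, so peaks were not assigned to genes, promoters, CpG islands or repeats. The planned gene lists and the planned feature classes were left out for that reason.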

Results

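5hmC and 5mC were profiled at 3 stages of a mouse secondary reprogramming system. In such a system, fibroblasts are derived from mice made from induced pluripotent stem (iPS) cells that carry doxycycline-inducible factors, so that the drug switches the same factors on again. Per the labels the factors were Tet1, Sox2, Klf4 and c-Myc. Tet1 is an enzyme that oxidises 5mC to 5hmC, and Oct4, a factor of the usual reprogramming set, is not among those named. The stages were fibroblasts at passage 4, the same kind of fibroblasts after 3 days of doxycycline (day 3), and an iPS cell line from this system at passage 10 to 15. Per the labels the medium changed with the doxycycline, and the iPS cells were grown on feeder cells and to a later passage. There was 1 library per stage and mark, 6 in all, and the read depth of each is unknown. Each statement below therefore compares single libraries, without replicate error.

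The series addresses how both marks are distributed as fibroblasts become iPS cells. The 5hmC lists held more peaks at each later stage, whereas the 5mC lists were longest at day 3 and shortest in iPS cells. 5hmC peaks numbered 42301 in fibroblasts, 116087 at day 3 and 174079 in iPS cells. 5mC peaks numbered 104011, 165869 and 61171 at the same stages. Relative to fibroblasts, the 5hmC list was 2.74 times as long at day 3 and 4.12 times as long in iPS cells. The 5mC list was 1.59 times as long at day 3 and 0.588 times as long in iPS cells. Fibroblasts and day-3 cells thus had more 5mC than 5hmC peaks, and iPS cells had more 5hmC than 5mC peaks. The 5hmC peaks covered 35.9 Mb, 127 Mb and 187 Mb of the genome at the 3 stages, and the 5mC peaks covered 111 Mb, 170 Mb and 59.7 Mb.

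Peak widths differed little between the lists, with medians from 815 bp for fibroblast 5hmC to 937 bp for fibroblast 5mC. Peaks of at least 3 kb made up 0.125% of the fibroblast 5hmC list, 1.69% at day 3 and 1.47% in iPS cells. Among 5mC peaks these shares were 0.810%, 0.962% and 0.369%. The median score, which depends on the depth of a library and was not compared between marks or stages, was 116.83 for day-3 5hmC, 107.31 for day-3 5mC and 105.86 for iPS 5hmC, 85.84 and 90.36 for the fibroblast 5hmC and 5mC lists, and 76.28 for iPS 5mC. The day-3 lists held 258 and 192 peaks with the recurring score of 3100, and the other lists held 33 to 45. With a score of at least 100 in each list, the iPS 5mC list was 0.392 times as long as that of fibroblasts and 0.199 times as long as that of day 3.

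**Figure D1:**
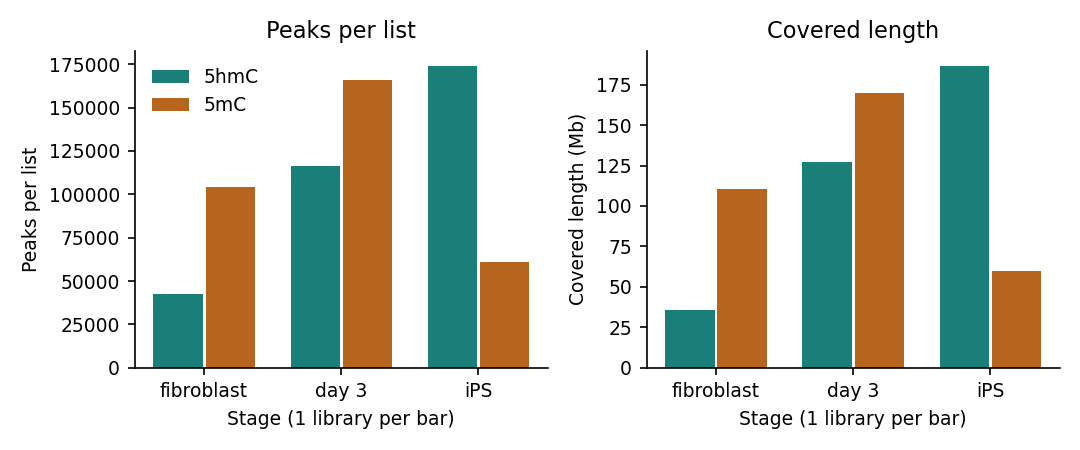
Number of peaks (left) and covered length in Mb (right) of the 5hmC (green) and 5mC (brown) list of each stage; each bar is 1 library, so there are no error bars. 5hmC went from 42301 to 174079 peaks between the fibroblast and iPS lists, and 5mC from 104011 to 61171.

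The first comparison followed 5hmC across the stages. Most 5hmC peaks of the later stages lay where the fibroblast list had none. At day 3, 86.8% of the 5hmC peaks (95% Wilson interval 86.6 to 87.0) had no fibroblast counterpart, and in iPS cells 84.3% had none (84.1 to 84.4). In the iPS list 58.7% of the peaks (58.5 to 58.9), 102188 peaks, occurred in neither earlier list. Of the fibroblast peaks, 35.9% (35.5 to 36.4) overlapped a day-3 peak and 63.7% (63.2 to 64.1) an iPS peak. Of the day-3 peaks, 48.3% (48.0 to 48.6) overlapped an iPS peak and 49.3% occurred at day 3 alone. Fibroblast peaks present in iPS cells but not at day 3 numbered 14540, or 34.4% of the fibroblast list, and those present at day 3 but not in iPS cells numbered 2800, or 6.62%. The iPS list was longer than the day-3 list, which by itself leads to more overlaps. Among the 4230 highest-scoring fibroblast 5hmC peaks, 97.4% overlapped an iPS 5hmC peak and 66.9% a day-3 5hmC peak. The shares of the same peaks on iPS and day-3 5mC peaks were 55.1% and 65.8%.

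Random placement of the counted peaks gave 13.1% for fibroblast peaks on iPS peaks, 8.86% for fibroblast on day-3 peaks and 14.3% for day-3 on iPS peaks. The observed shares were 4.84, 4.05 and 3.37 times as large. Moving the peaks by 10 to 50 kb gave 23.7%, 14.4% and 30.0%, so that the observed shares were 2.69, 2.49 and 1.61 times as large. No placement of either kind reached the observed share. With the 42301 best-scoring peaks of each list, the share of fibroblast peaks was 15.2% on day-3 and 21.3% on iPS peaks, and that of day-3 peaks on iPS peaks was 26.4%, the highest of the 3.

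**Figure D2:**
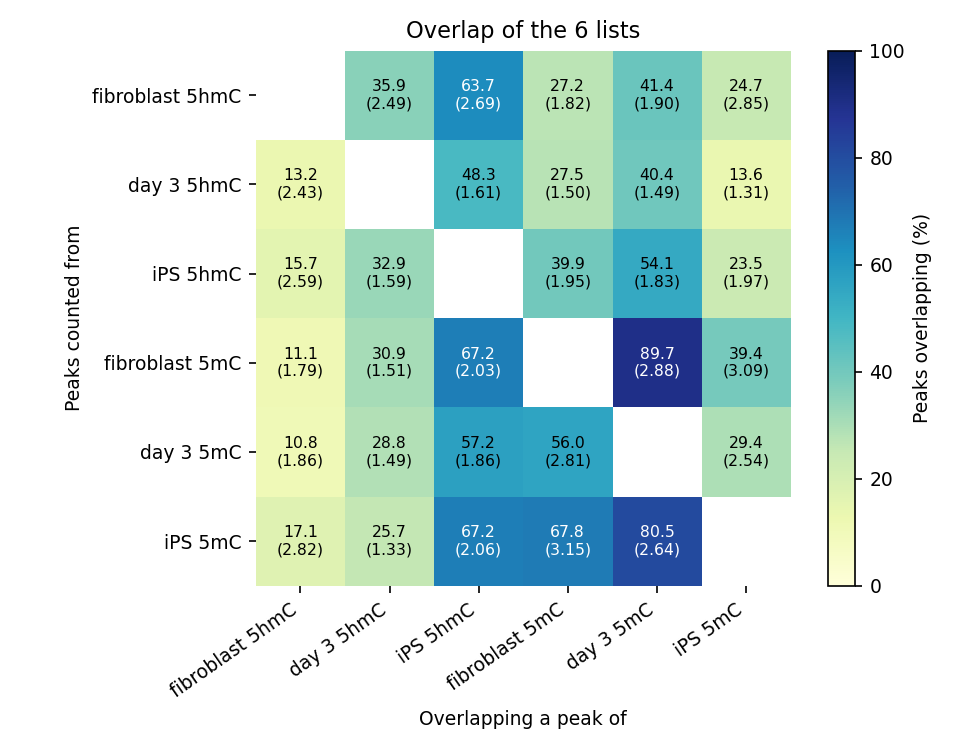
Percent of the peaks of the list in each row that overlap, by at least 1 bp, a peak of the list in each column; below it in parentheses is the observed share divided by the mean share after moving the counted peaks by 10 to 50 kb. The highest share is that of fibroblast 5mC peaks on day-3 5mC peaks (89.7%), and fibroblast 5mC peaks overlapped iPS 5hmC peaks in 67.2% of cases.

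The same comparison for 5mC gave a different picture. Fibroblast 5mC peaks were nearly all present at day 3, at 89.7% (89.5 to 89.8), and 39.4% (39.1 to 39.6) were present in the shorter iPS list. Of the fibroblast peaks 52.0%, 54041 peaks, occurred in fibroblasts and at day 3 but not in the iPS list, and 37.7% occurred at all 3 stages. The iPS list consisted mainly of peaks already present in the earlier lists, as 67.8% of iPS 5mC peaks (67.4 to 68.1) lay on fibroblast and 80.5% (80.2 to 80.8) on day-3 peaks, while 16.6% occurred in iPS cells alone. At day 3, 38.3% of the 5mC peaks occurred at that stage alone. Random placement gave 13.8% for fibroblast peaks on day-3 peaks and 5.15% for fibroblast on iPS peaks, and moving peaks by 10 to 50 kb gave 31.1% and 12.7%. With the 61171 best-scoring peaks of each 5mC list, 75.2% of fibroblast peaks overlapped day-3 peaks and 50.3% overlapped iPS peaks, while 51.8% of iPS peaks lay on fibroblast and 51.3% on day-3 peaks.

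Counted over windows of 100 kb, the lists differed in most windows. From fibroblasts to iPS cells, 5hmC covered more base pairs in 15465 windows and fewer in 4041, so that 79.3% of the windows that differed had more. 5mC covered more in 2315 windows and fewer in 14375, so that 13.9% had more. From fibroblasts to day 3 the shares of windows with more were 73.1% for 5hmC and 91.8% for 5mC, and from day 3 to iPS cells they were 62.5% and 3.39%. The 5mC shares from fibroblasts and from day 3 to iPS cells were 4.67% and 0.600% over windows of 1 Mb, and the share from day 3 was 2.17% over 100 kb with a score of at least 100.

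A gain or loss below is the difference in covered length between the iPS and the fibroblast list, without a test. The largest 5hmC gain was on chromosome 5 from 116300001 to 116400000, where 5hmC peaks covered 6.10 kb in fibroblasts, 21.2 kb at day 3 and 73.5 kb in iPS cells. In the same window 5mC peaks covered 65.4 kb in fibroblasts, 68.1 kb at day 3 and 41.0 kb in iPS cells. The next gains were on chromosome 11 from 117900001 to 118000000, with 6.17 kb of 5hmC in fibroblasts and 71.5 kb in iPS cells, and on chromosome 15 from 58800001 to 58900000, with 1.91 kb and 65.9 kb. Both windows were already widely covered by 5mC in fibroblasts, at 51.8 kb and 37.3 kb, against 32.3 kb and 22.1 kb in iPS cells. The largest 5hmC losses were on chromosome 1 from 90100001 to 90200000, with 86.2 kb and 50.4 kb, on chromosome 3 from 25400001 to 25500000, with 40.7 kb and 9.66 kb, and on chromosome X from 120100001 to 120200000, with 11.3 kb and 0 kb. In these 3 windows 5mC peaks covered 88.8 kb, 39.5 kb and 9.23 kb in fibroblasts and 82.3 kb, 37.7 kb and 8.39 kb in iPS cells.

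The largest 5mC losses were on chromosome 8 from 117300001 to 117400000, with 33.5 kb in fibroblasts, 35.1 kb at day 3 and 1.56 kb in iPS cells, on chromosome 4 from 140800001 to 140900000, with 35.9 kb, 41.8 kb and 6.64 kb, and on chromosome 2 from 165600001 to 165700000, with 38.1 kb, 48.2 kb and 9.91 kb. In the windows on chromosomes 4 and 2, 5hmC peaks covered 12.5 kb and 2.88 kb in fibroblasts, 41.3 kb and 43.7 kb at day 3, and 40.7 kb and 44.3 kb in iPS cells. In the window on chromosome 8, 5hmC covered 3.15 kb, 8.88 kb and 8.37 kb. The largest 5mC gains were smaller. They were on chromosome 2 from 77700001 to 77800000, with 4.46 kb in fibroblasts and 22.9 kb in iPS cells, on chromosome Y from 2800001 to 2900000, with 32.7 kb and 48.0 kb, and in the last X window from 166400001 to 166500000, with 23.2 kb and 31.6 kb. 5hmC peaks covered 32.6 kb of the Y window and 18.98 kb of the X window in fibroblasts. In iPS cells they covered 40.3 kb and 26.9 kb, so both marks covered more there and these gains were not particular to 5mC. In the window on chromosome 2, 5hmC covered 0 kb in fibroblasts and 9.22 kb in iPS cells.

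The best-scoring fibroblast 5hmC peak was on chromosome 1 from 90151099 to 90166878, and the other 5 lists had an overlapping peak there. The same held for the best peaks of the day-3 5mC list, on chromosome 7 from 7230164 to 7231398, and of the iPS 5mC list, on chromosome 18 from 3004068 to 3006765. The best fibroblast 5mC peak, on chromosome 4 from 132616569 to 132622689, overlapped peaks of 4 other lists. The best 5hmC peaks at day 3, on chromosome 3 from 126325534 to 126327856, and in iPS cells, on chromosome 2 from 76546812 to 76551159, overlapped peaks of 3 other lists each.

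The second comparison set both marks against each other within a stage. 5hmC peaks lay on 5mC peaks more often than by placement at each stage, and most 5hmC peaks lay outside 5mC peaks. The share of 5hmC peaks on a 5mC peak of the same stage was 27.2% (26.7 to 27.6) in fibroblasts, 40.4% (40.1 to 40.7) at day 3 and 23.5% (23.3 to 23.7) in iPS cells. These shares were 3.37, 2.97 and 4.59 times those of random placement and 1.82, 1.49 and 1.97 times those after moving the peaks by 10 to 50 kb. Neither placement keeps the CpG content of the peaks, on which capture depends. The excess over placement therefore cannot tell a shared ease of capture from marks that occur together. The order of the stages changed when lists of equal length were compared. With the 42301 best-scoring peaks of each of the 6 lists, the shares were 13.2% in fibroblasts, 22.3% at day 3 and 36.3% in iPS cells, so that iPS cells had the highest share and not the lowest. The lowest score kept differed between these sets. The fibroblast 5hmC set was the whole list, whereas the day-3 and iPS 5hmC sets ended at 162.8 and 187.58. The 5mC sets ended at 105.03 in fibroblasts, 190.29 at day 3 and 62.96 in iPS cells. No expectation by placement is given for these shares, so the changed order was not read as a difference between stages. With a score of at least 100 in each list, the shares were 18.4% in fibroblasts, 31.7% at day 3 and 13.6% in iPS cells, again lowest in iPS cells. Counted from the 5mC side, 11.1% of 5mC peaks lay on 5hmC peaks in fibroblasts, 28.8% at day 3 and 67.2% in iPS cells. These shares were 13.1%, 22.4% and 38.4% with the 42301 best-scoring peaks of each list, and the fibroblast share was 7.04% with a score of at least 100.

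The third comparison followed the fibroblast 5mC peaks to the later 5hmC lists. In fibroblasts, 92420 of the 104011 5mC peaks had no overlapping 5hmC peak. Of these, 27.7% (27.4 to 28.0) had a 5hmC peak at day 3 and 65.0% (64.7 to 65.3) had one in iPS cells. At day 3 the 5mC peak was usually still listed, both with and without a new 5hmC peak. With 5hmC, 25.4% had both marks and 2.29% had no 5mC. Without 5hmC, 64.1% had 5mC and 8.20% had neither mark. The kept 5mC was thus not particular to the peaks with new 5hmC. In iPS cells 37.5% (37.1 to 37.8) had 5hmC without 5mC, 27.6% had both, 9.66% had 5mC without 5hmC and 25.3% had neither. Of the 60088 peaks with 5hmC in iPS cells, 66.7% had no 5hmC peak at day 3. Peaks with 5hmC at day 3 had it in iPS cells in 78.0% of cases (77.5 to 78.5), against 60.02% (59.6 to 60.4) of those without 5hmC at day 3. The share with 5hmC and without 5mC in iPS cells was 21.9% with the 42301 best-scoring peaks of each list. The iPS 5mC list was shorter than that of day 3 (61171 against 165869 peaks), which leaves more peaks without 5mC. Where 5mC was present in iPS cells, 25475 peaks had 5hmC and 8925 had none. Where 5mC was absent, 34613 had 5hmC and 23407 had none. 5hmC was thus more frequent where 5mC was present, and a replacement of 5mC by 5hmC cannot be read from these shares.

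**Figure D3:**
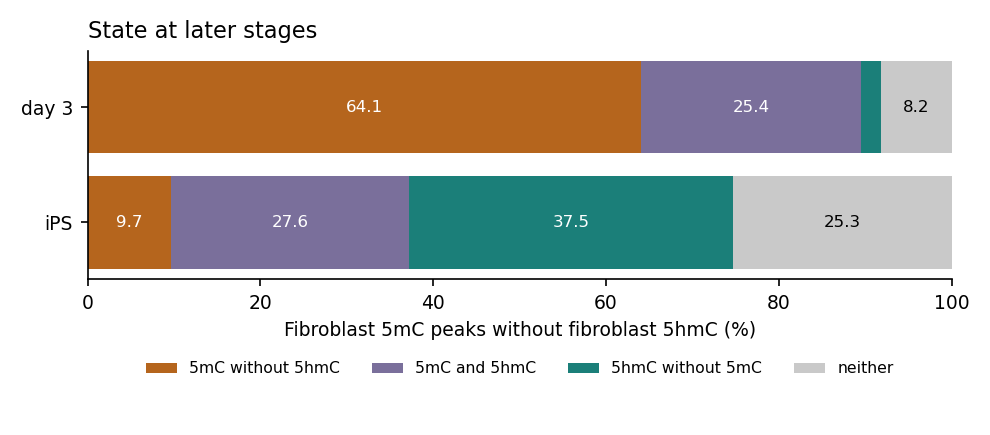
State at day 3 and in iPS cells of the 92420 fibroblast 5mC peaks without a fibroblast 5hmC peak, in percent of these peaks, by the presence of an overlapping 5mC or 5hmC peak at the later stage. The part with 5hmC but no 5mC was 2.29% at day 3 and 37.5% in iPS cells, and the part with neither mark was 8.20% and 25.3%. The iPS 5mC list was shorter than that of day 3 (61171 against 165869 peaks), which leaves more peaks without 5mC.

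Over all fibroblast 5mC peaks, 30.9% (30.6 to 31.1) overlapped a day-3 5hmC peak and 67.2% (66.9 to 67.4) an iPS 5hmC peak. These shares were 3.14 and 4.63 times those of random placement and 1.51 and 2.03 times those after moving the peaks by 10 to 50 kb. With equal numbers of best-scoring peaks they were 19.9% and 48.3%. Of the 10401 highest-scoring fibroblast 5mC peaks, 48.3% overlapped day-3 5hmC and 93.6% overlapped iPS 5hmC.

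Traced backwards, 25.03% of the 100738 5hmC peaks gained by day 3 lay on a fibroblast 5mC peak. Gained peaks on fibroblast 5mC were present in iPS cells in 78.3% of cases (77.7 to 78.8), and gained peaks off it in 31.4% (31.1 to 31.8). For all day-3 5hmC peaks, the expectation by moved peaks was 30.0% on iPS 5hmC peaks, close to the share off fibroblast 5mC. No placement was run for the gained peaks on or off fibroblast 5mC, so neither share has its own expectation. The 31.4% was therefore not read as persistence of 5hmC. The share on fibroblast 5mC was also the higher in each of 5 equal groups of day-3 peaks ranked by score. In the lowest-scoring group the shares were 76.2% and 23.9%, and in the highest-scoring group they were 81.7% and 47.6%. With equal numbers of best-scoring peaks the shares were 60.2% and 14.3%. Counted from the 5mC side, fibroblast 5mC peaks without 5hmC in fibroblasts and at day 3 had iPS 5hmC in 60.02% of cases. The contrast therefore includes the general overlap of fibroblast 5mC with iPS 5hmC, which grouping by day-3 score does not remove. Gained peaks present in iPS cells had a median width of 1003 bp and a median score of 142.2, against 874 bp and 101.34 for those absent from the iPS list. Of the 102188 5hmC peaks found in iPS cells alone, 38.5% lay on fibroblast 5mC and 52.2% on day-3 5mC, and 54.9% lay on at least 1 of these.

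**Figure D4:**
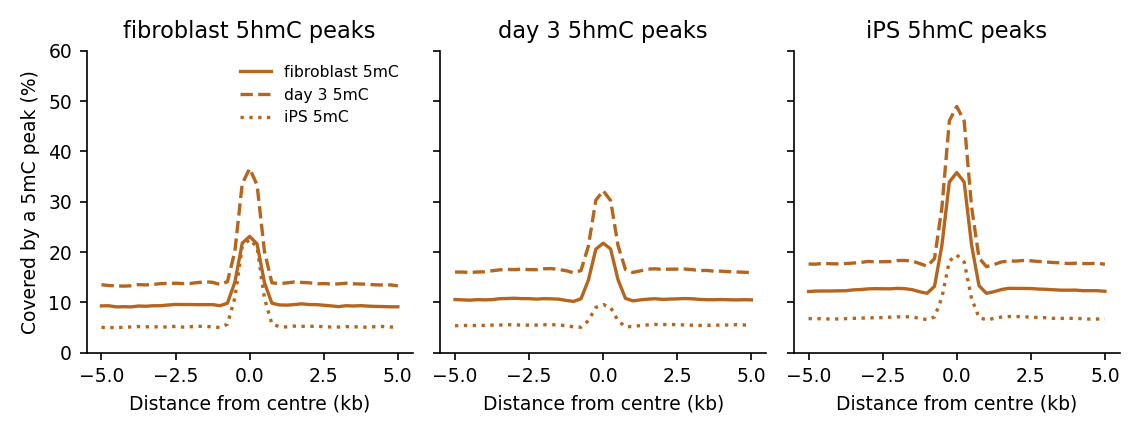
Percent of 5hmC peaks of each stage (panels) that have a 5mC peak of fibroblasts (solid), day 3 (dashed) or iPS cells (dotted) at a given distance in kb from the 5hmC peak centre. Fibroblast 5mC covered 35.8% of iPS 5hmC centres against 12.2% of positions 5 kb away, and 21.8% of day-3 5hmC centres against 10.6% of positions 5 kb away.

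5mC was found more often at the centre of 5hmC peaks than beside them. Fibroblast 5mC peaks covered 35.8% of the centres of iPS 5hmC peaks and 11.8% of the positions 1 kb from them. For day-3 5hmC centres these values were 21.8% and 10.3%, and for fibroblast 5hmC centres they were 23.1% and 9.44%.

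Across chromosomes, the autosomes differed moderately and chromosome X stood apart. Peak density per Mb on single autosomes ranged from 0.663 times the autosomal mean, on chromosome 3 in iPS 5mC, to 1.42 times, on chromosome 11 in iPS 5hmC. Chromosome X makes up 6.26% of the span that the peaks cover. It held 297 fibroblast 5hmC peaks, or 0.702% of the list (0.627 to 0.786), 1004 at day 3, or 0.865% (0.813 to 0.920), and 422 in iPS cells, or 0.242% (0.220 to 0.267). For 5mC it held 243 peaks, or 0.234% (0.206 to 0.265), 605, or 0.365% (0.337 to 0.395), and 108, or 0.177% (0.146 to 0.213). X density was thus 0.106, 0.131 and 0.0364 times the autosomal density for 5hmC and 0.0350, 0.0548 and 0.0265 times for 5mC. With a score of at least 100, the X share of 5hmC was 0.723% in fibroblasts and 0.678% at day 3, so that day 3 was no longer above fibroblasts. In the iPS lists the X share was then 0.137% for 5hmC and 0.254% for 5mC, so that the order of the marks turned. These shares rest on 127 and 45 X peaks, and the setting kept 53.2% of the iPS 5hmC list and 29.0% of the iPS 5mC list. Chromosome Y, of which the lists span 2.86 Mb, held 39 to 70 peaks, or 0.189 to 1.41 times the autosomal density. With a score of at least 100 the Y density was 2.51 times the autosomal density for fibroblast 5hmC, where it had been 1.41, 0.840 times for fibroblast 5mC, where it had been 0.422, and 1.72 times for iPS 5mC, where it had been 0.690.

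**Figure D5:**
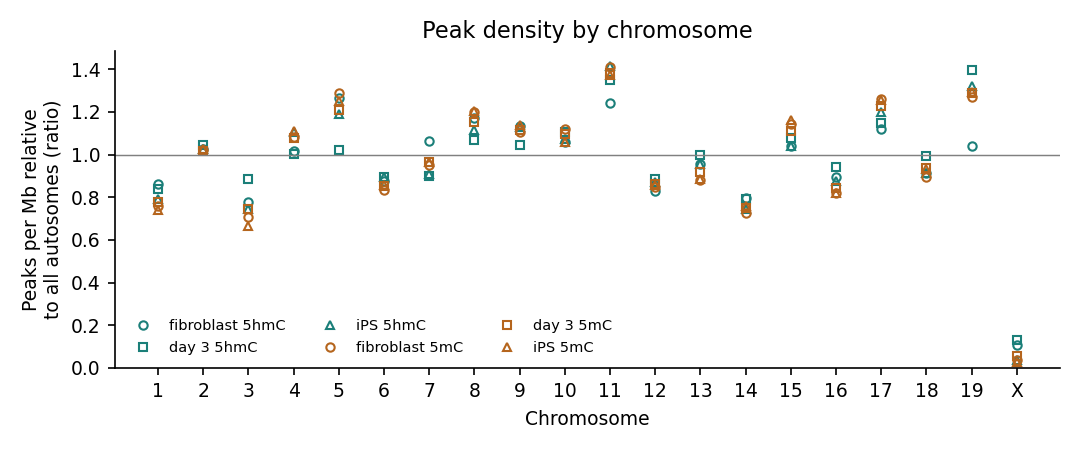
Peaks per Mb of each chromosome divided by the peaks per Mb of all autosomes of the same list (ratio, line at 1), for 5hmC (green) and 5mC (brown) at each stage. On chromosome X the 6 ratios lie between 0.0265 and 0.131, below those of each autosome.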

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

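No test in this part was chosen after its result was seen. The marks went in opposite directions between the same stages, which is what singled out the results in this part. Each rests on 1 library per stage and mark, and the difference between the marks was not tested. From fibroblasts to iPS cells the number of 5hmC peaks was 4.12 times as high and that of 5mC peaks 0.588 times as high. From day 3 to iPS cells the ratios were 1.4996 and 0.369. With a score of at least 100 the 5mC ratios were 0.392 and 0.199. Over windows of 100 kb, 79.3% of those that differed between fibroblasts and iPS cells had more 5hmC in iPS cells and 13.9% had more 5mC. From day 3 to iPS cells, 62.5% had more 5hmC and 3.39% had more 5mC. Over windows of 1 Mb the 5mC shares were 4.67% and 0.600%, and with a score of at least 100 the share from day 3 was 2.17%.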

How the results depend on the processing

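The expectation by moved peaks was chosen after the results had been seen. Read depth is unknown for each library and is the main limit, because a deeper library gives more peaks and higher scores. The direction of each ratio of peak number and covered length held with a score of at least 100, with joined peaks and on autosomes, the side of 50% of each window share held with a score of at least 100 and with windows of 1 Mb, and the difference in each of the 12 named windows kept its sign with a score of at least 100. Joining peaks within 1 kb or keeping autosomes alone moved none of the 12 ratios by over 1.5 times. With a score of at least 100, the 5mC peak number in iPS cells was 0.392 times that of fibroblasts and 0.199 times that of day 3. The same setting gave windows with more 5hmC in 79.4% (fibroblasts to day 3), 84.7% (fibroblasts to iPS) and 57.6% (day 3 to iPS) of those that differed, and more 5mC in 93.4%, 10.5% and 2.17%. Windows of 1 Mb gave 81.1%, 81.9% and 65.6% for 5hmC and 98.4%, 4.67% and 0.600% for 5mC. The X share became 0.678% and 0.308% for day-3 5hmC and 5mC and 0.137% and 0.254% for iPS 5hmC and 5mC with a score of at least 100, so that in iPS cells 5mC then had the higher share. The fibroblast 5hmC share was 0.723% in this setting, above that of day 3, whereas it was below with all peaks. For fibroblast 5hmC on day-3 and on iPS 5hmC, and for day-3 on iPS 5hmC, the shares were 32.9%, 60.9% and 41.3% with an overlap of at least 50%, 33.3%, 61.4% and 41.9% by peak centre, 29.2%, 60.8% and 38.5% with a score of at least 100, and 15.2%, 21.3% and 26.4% with equal numbers of best-scoring peaks, where day-3 on iPS peaks had the highest of the 3 shares. For fibroblast 5mC on day-3 and on iPS 5mC they were 88.8% and 35.9%, 88.6% and 36.5%, 93.6% and 27.6%, and 75.2% and 50.3% in the same order of settings. 5hmC on 5mC of the same stage gave 23.1%, 31.6% and 18.5% for fibroblasts, day 3 and iPS cells with an overlap of at least 50%, 18.4%, 31.7% and 13.6% with a score of at least 100, and 13.2%, 22.3% and 36.3% with equal numbers, which put iPS cells first and not last. Fibroblast 5mC on day-3 and on iPS 5hmC gave 24.8% and 63.3%, 26.4% and 67.5%, and 19.9% and 48.3% in the same 3 settings. Day-3 5hmC gains on and off fibroblast 5mC were present in iPS cells, again in that order, in 74.1% and 28.1%, 76.5% and 26.8%, and 60.2% and 14.3%, and fibroblast 5mC peaks had 5hmC without 5mC in iPS cells in 46.3% with a score of at least 100 and 21.9% with equal numbers. Of the 30 shares between lists, 30 were lower with an overlap of at least 50%, 25 with a score of at least 100 and 20 with equal numbers, and by peak centre 12 of 12 were lower. Expectation by moved peaks lowered each of the 30 observed-over-expected ratios by over 1.5 times and left each above 1. The cause was not tested. Alternatives for genomic features, promoters and gene bodies were not run, since no mm9 annotation was used here. No paired analysis was possible because each stage and mark has 1 library.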

Other observations

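The tests of explanations in this part, apart from the setting with equal numbers of best-scoring peaks, and the regions it names, apart from the last X window, were chosen after the results had been seen. Some regions had far more 5hmC at day 3 than at either other stage. The window with the most 5hmC at day 3 above both other stages was on chromosome 3 from 126300001 to 126400000, with 66.5 kb covered at day 3, 3.203 kb in fibroblasts and 13.6 kb in iPS cells. The same window had 7.17 kb of 5mC in fibroblasts, 10.4 kb at day 3 and 1.51 kb in iPS cells, and it also holds the best-scoring day-3 5hmC peak. The next were on chromosome 11 from 76100001 to 76200000, with 78.3 kb at day 3 against 4.53 kb and 45.4 kb, and on chromosome 1 from 154400001 to 154500000, with 62.7 kb against 1.44 kb and 31.2 kb.

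On chromosome X, day-3 5hmC peaks occurred in 385 of 1665 windows, against 176 in fibroblasts and 234 in iPS cells. These numbers were not scaled to list length, and the day-3 5hmC list was 2.74 times as long as that of fibroblasts. With a score of at least 100, the X share of 5hmC was lower at day 3 (0.678%) than in fibroblasts (0.723%). The windows from 11600001 to 11700000 and from 11700001 to 11800000 had 23.4 kb and 16.3 kb at day 3, against 0.725 kb and 0 kb in fibroblasts and 11.02 kb and 5.03 kb in iPS cells. The windows from 139100001 to 139200000 and from 139200001 to 139300000 had 16.1 kb and 17.3 kb at day 3, against 0.761 kb and 0 kb in fibroblasts and 0 kb and 1.46 kb in iPS cells. The window from 99100001 to 99200000 had 16.2 kb at day 3, 0.676 kb in fibroblasts and 0 kb in iPS cells. The last X window was covered at 18.98 to 31.6 kb in each of the 6 lists. Why chromosome X held few peaks was not tested.

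iPS 5hmC peaks lay on fibroblast 5mC peaks more often (39.9%) than day-3 5hmC peaks did (27.5%). Moving the peaks by 10 to 50 kb gave 20.4% for iPS and 18.3% for day 3, and the observed gap was above the widest gap of 100 such placements by 9.93 percentage points with all peaks and by 22.1 with 42301 best-scoring peaks per list, which argues against a shared preference for the same broad regions as the whole cause and leaves it open as a part. With all peaks, the iPS list labelled 5hmC lay on day-3 5hmC peaks more often than that labelled 5mC (32.9% against 25.7%). It lay on day-3 5mC peaks less often (54.1% against 80.5%), but its share on fibroblast 5hmC peaks was lower (15.7% against 17.1%, a difference of -1.40 percentage points). With 42301 best-scoring peaks per list, this difference was 1.89 percentage points (20.9% against 19.02%). The shares were then 26.4% against 13.1% on day-3 5hmC, 46.6% against 49.7% on fibroblast 5mC and 46.8% against 49.2% on day-3 5mC. The values at equal numbers go with the given labels. Exchanged labels of the iPS libraries stay open, because the all-peaks share on fibroblast 5hmC goes the other way. Also open is whether 5hmC formed at sites methylated in fibroblasts, which may follow from the induced Tet1, or whether 5mC DNA was captured in the iPS 5hmC library, since 45.3% of the iPS 5hmC peaks on fibroblast 5mC were also in the shorter iPS 5mC list and its depth is unknown.

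Fibroblast 5hmC peaks recurred in the iPS list (63.7%) more often than in the day-3 list (35.9%), although day 3 is the nearer stage. The gap was 27.8 percentage points with all peaks and 12.4 with the iPS list reduced to its 116087 best-scoring peaks, where the iPS share was 48.3%. With 42301 best-scoring peaks per list the shares were 21.3% and 15.2%, a gap of 6.13 percentage points. The gap shrank when list lengths were made equal but kept its direction, so the length of the iPS list stays open as a part of the explanation. A difference of the day-3 library in preparation or depth, and a temporary absence of 5hmC from these sites during induction, were not tested and stay open with 1 library per stage. The iPS cells were grown on feeder cells, and whether DNA of these cells contributed to the iPS lists was not tested. This also stays open for the overlaps of iPS peaks with fibroblast 5mC peaks.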
